A study of Mus musculus with 26 samples.

How the data were processed

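Messenger RNA was measured in 26 single inner cell masses (ICMs) of CD-1 mouse embryos, 1 library per ICM, by FLASH-seq, a full-length single-cell RNA-seq method used here on whole ICMs. Per the labels, morulae of embryonic day 2.75 were cultured for 24 hours in 1 of 4 conditions. These were the DMSO vehicle (5 ICMs), LY294002, an inhibitor of PI3K, at 10 µM (LY, 7 ICMs), FGF4 with heparin at 1 µg/ml (FGF4, 8 ICMs), and both (LY+FGF4, 6 ICMs). The zona pellucida had been taken off and the outer cells lysed by immunosurgery. Embryos of 5 litters were pooled before they were shared out between conditions, so each library is a separate embryo and its litter is unknown. All labels carry 1 date and name no batch. Replicate numbers repeat between groups. Libraries of the same number did not resemble each other (31 pairs, median r of the residuals -0.00406), so they were not treated as pairs.

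The values are TPM (transcript abundance scaled to a fixed total per library) per gene symbol, computed by the authors. Per the labels, reads were trimmed and de-duplicated, and the processing notes name STAR, RSEM and the mm10 genome. Their versions, the annotation and the strandedness are not given in the sources used here. The table has 55254 symbols, and each library adds up to between 1000000 and 1000001 TPM, so values are shares of a library and hold no read number. Coordinates are those of GENCODE M21 on GRCm38, which matched 53255 symbols and may not be the annotation the authors used. The 13 mitochondrially encoded genes matched 0 symbols and were not analysed here. The number of reads behind each library was estimated from the spacing of the TPM values of 6734 genes with 1 annotated transcript, and it ranged from 290884 to 1523333. These are estimates under an assumed fragment length, and no counting intervals were derived from them.

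Differential expression was tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with 12034 genes at TPM of at least 1 in at least 5 libraries. The 26 libraries were fitted together with 1 mean per group, and the empirical Bayes step used the trend and robust options. Tests were two-sided at a Benjamini-Hochberg adjusted p under 0.05, for 5 pairwise comparisons and for the interaction, which is the LY effect with FGF4 minus the LY effect without it. All log2 fold changes are on the log2(TPM + 1) scale, which shrinks those of genes with low TPM. Where 1 group was at 0 in every library, no fold is given.

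Gene lists were written by hand before the data were examined, from textbook knowledge and not from these libraries. 26 lists with at least 5 tested members were tested with camera (preset correlation 0.01), adjusted over the lists of a comparison. The test with an estimated correlation and fry, which asks whether members move on balance in 1 direction, were run beside it. Camera compares members with all other genes, so a list called higher can also be one that fell less than the rest. Fry results are given where a list called by camera was not called by fry. The lists cover epiblast, primitive endoderm, trophectoderm and oocyte-derived transcripts, core naive and formative pluripotency, FGF/ERK, FOXO, WNT, BMP/TGF-beta, Hippo/YAP and p53 targets, and components of the FGF and PI3K pathways. They also cover ATF4 and amino acid genes, sterol and lipid synthesis, glycolysis, oxidative phosphorylation, ribosome biogenesis, lysosome and autophagy, S phase, G2/M, the unfolded protein response, immediate early and heat shock genes, basement membrane and matrix, and apoptosis regulators. The primitive endoderm and basement membrane lists share 8 genes. A list of cleavage-stage genes had 1 tested member, and its test was not run. 4 Y-linked genes are given as values only.

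A list score is the mean log2(TPM + 1) of the tested members in a library, with a value of 0 entering as 0. Scores were compared with two-sided exact permutation tests, adjusted over 25 tests for 5 lists, and over 5 tests for the epiblast minus the primitive endoderm score. Effects were compared across genes by Pearson's r and Spearman's rho beside 99 regroupings of the libraries. For the contrasts that share the DMSO libraries, groups without an effect were simulated with each group's own spread. A first simulation with the pooled spread, replaced after its result was seen, had given a higher r. The named genes follow a rule fixed before the data were examined. The rule takes 14 lineage and signalling genes in every comparison, of which Irs2 did not pass the expression filter. It then takes the 8 largest and 8 smallest log2 fold changes among genes past the threshold with mean TPM of at least 5 in the higher group. Predicted symbols, Y-linked genes and Xist were left out of these. It adds the 4 members with the smallest p of each called list. Some genes that the rule names are not reported here. Others fall outside the rule and were named after their values were seen, to complete lists of called members or as examples. These are Prdm14, Etv4 and Spred1 for FGF4 against DMSO, Slc3a2 for LY against DMSO, Ddit4 for LY+FGF4 against FGF4, Lif, Spred1 and Tdgf1 for LY+FGF4 against LY, and Lrp2 for LY+FGF4 against DMSO.

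The fit was tested on simulated data in which 100 genes changed 2-fold and 100 changed 4-fold. With equal spread in all groups, false calls were 0 to 9.18% of calls. With each group's own spread, and changed genes drawn from all tested genes, they were 8.51% for LY against DMSO, 10.3% for FGF4 against DMSO and 6.25% for the interaction. They came to 57.7%, 52.5% and 32.7% for LY+FGF4 against FGF4, LY and DMSO, since the LY+FGF4 libraries vary more than the pooled spread. These were 71, 53 and 18 false calls. Apart from the changed genes, simulated values were drawn around 1 mean per gene for all groups. No transcripts were lost in them and no whole group was shifted, so false calls from such loss or shift are not counted. With more genes truly changed, the same number of false calls would be a smaller share. With changed genes of mean TPM of at least 30, the shares were 43.9%, 30.7% and 16.3%, and 16.7% for the interaction. Of 100 genes changed 4-fold and drawn from all tested genes, the fit found 14 to 40 with each group's own spread. Of 100 changed 2-fold it found 1 to 14. With changed genes of mean TPM of at least 30 it found 36 to 72 and 9 to 32, and none was called in the wrong direction.

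Alternatives were other pseudocounts, filters, scalings and weights, covariates, a replicate block, fits of 2 groups only, a rank test and leaving out each library in turn. Further ones, added after the data had been seen, used the estimated read number, abundant genes only, or fewer libraries. The values were handled with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statmod 1.5.0, and drawn with matplotlib 3.10.9.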

Results

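The table held TPM values of 26 single-ICM libraries, in a design that crossed LY, an inhibitor of PI3K, with added FGF4. DMSO had 5 ICMs, LY 7, FGF4 8 and LY+FGF4 6. The median estimated read number was 531007 in DMSO, 375636 in LY, 454097 in FGF4 and 360209 in LY+FGF4. The median number of genes at TPM of at least 1 was 10692 in DMSO, 10089 in LY, 10504.5 in FGF4 and 8650.5 in LY+FGF4. 6 libraries listed fewer than 9000 genes, namely replicates 2 and 3 of FGF4 and replicates 2, 3, 5 and 8 of LY+FGF4. Without them LY+FGF4 holds only replicates 6 and 7, so results without the 6 libraries rest on these for that group. All 10 widely used genes that were looked at were above 0 in each of the 26 libraries. The median correlation between libraries of a group was 0.892 in DMSO, 0.852 in LY, 0.802 in FGF4 and 0.751 in LY+FGF4. Y-linked transcripts at TPM of at least 5 were seen in 2 of 5 DMSO, 5 of 7 LY, 2 of 8 FGF4 and 1 of 6 LY+FGF4 libraries. Xist at TPM of at least 5 was seen in 3, 2, 7 and 4 libraries in the same order. FGF4 replicate 1 had both, and 1 LY+FGF4 library had neither.

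**Figure D1:**
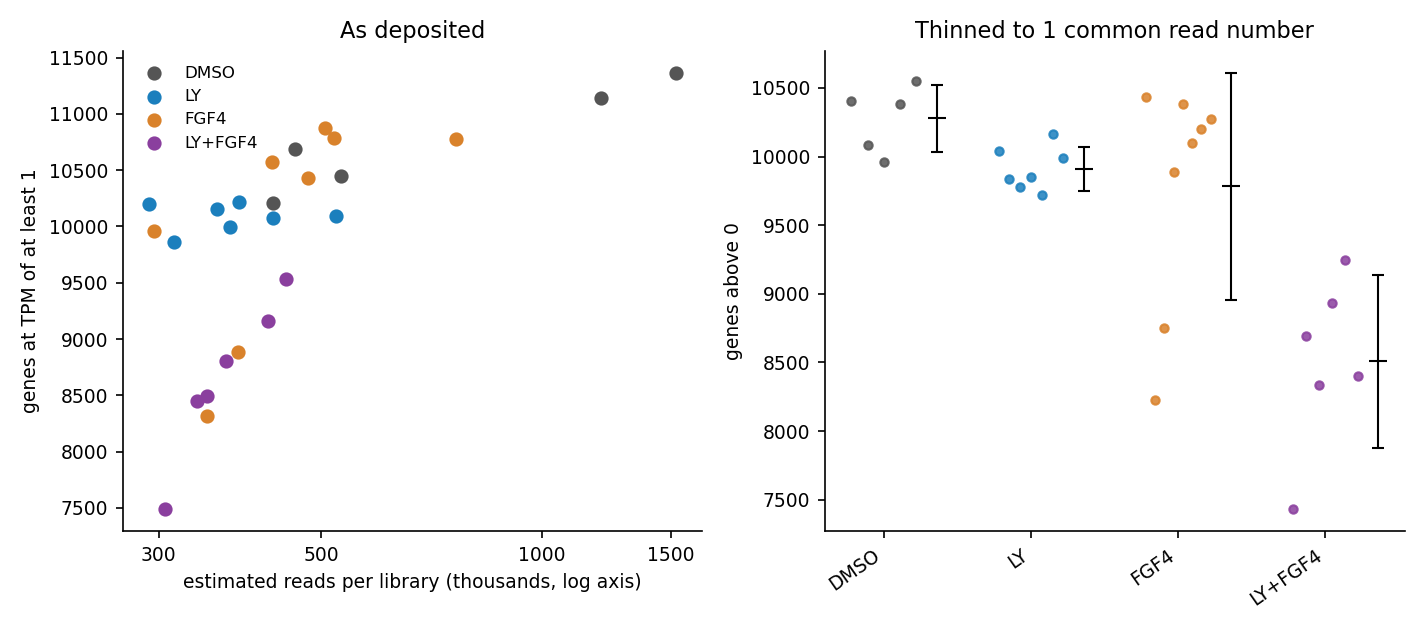
Left, genes at TPM of at least 1 against the estimated number of reads (kilo-reads, log axis), 1 point per library. Right, genes above 0 after every library was thinned to 1 common estimated read number, with mean ± SD beside the points; the highest LY+FGF4 library, at 9247 genes, lies below the lowest DMSO library, at 9963.

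Added FGF4 was compared with DMSO to ask how the ICM responds to an excess of this growth factor, which epiblast cells make and which drives primitive endoderm. Epiblast genes were lower and primitive endoderm genes higher in FGF4-treated ICMs. Nanog, a transcription factor of the epiblast, averaged 178 ± 20.8 TPM (SD, n = 5) in DMSO and 28.7 ± 60 TPM (n = 8) with FGF4. The embryo's own Fgf4 transcript averaged 47.7 ± 21.8 TPM in DMSO and was listed at 0 in 7 of 8 FGF4 libraries. Sox17, a transcription factor of primitive endoderm, averaged 151 ± 125 TPM in DMSO and 667 ± 179 TPM with FGF4, and Gata4, another one, 8.94 ± 11.5 and 126 ± 52.9 TPM. Dusp4, a phosphatase that is induced by and acts on ERK signalling, averaged 28.4 ± 20 and 325 ± 155 TPM, and every FGF4 library was above every DMSO library.

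On GRCm38, Nanog spans 122707489 to 122714633 on chromosome 6 and Fgf4 144847367 to 144865243 on chromosome 7. Sox17 spans 4490931 to 4497354 on chromosome 1, Gata4 63198922 to 63271692 on chromosome 14, and Dusp4 34807297 to 34819894 on chromosome 8. All of these are protein-coding genes, and TPM values are per gene, not per isoform.

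Of 29 primitive endoderm genes, 9 rose and none fell with FGF4, and 14 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.14e-12, and adjusted p = 0.0242 with an estimated correlation). They included Gata4 (log2 fold change 4.18, adjusted p = 0.00401), Sox17 (2.76, adjusted p = 0.0361), Serpinh1, a collagen chaperone (4.57), and Dkk1, a secreted WNT inhibitor (3.45). Gata6, another gene of this list, did not pass the test (0.29, adjusted p = 0.688), nor did Pdgfra, a receptor of primitive endoderm (2.11, adjusted p = 0.057), which passed in 5 other settings. Of 24 basement membrane and matrix genes 7 rose, and 8 when adjusted over the list alone, among them the laminin genes Lama1 (4.17) and Lamc1 (2.64), the collagen gene Col4a1 (2.28), the perlecan gene Hspg2 (3.02) and P4ha1 (1.38). That list gave a camera adjusted p of 2.70e-06, and adjusted p = 0.0523 with an estimated correlation.

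Of 14 epiblast genes, 5 fell and none rose, and 10 fell when adjusted over the list alone (camera adjusted p = 6.06e-08, and adjusted p = 0.0189 with an estimated correlation). These were Fgf4 (-5.15, adjusted p = 8.85e-07), Klf2 (-5.31), Nanog (-4.28, adjusted p = 0.0156), Prdm14 (-2.64) and Utf1 (-1.37). Sox2 (-1.03, adjusted p = 0.582) and the pluripotency factor Pou5f1 (-0.47, adjusted p = 0.0967) did not pass the test. Among 22 FGF/ERK targets, 4 rose, namely Dusp4 (3.90), Etv4 (3.07), Spred1 (2.56) and Spry4 (2.30), and the proto-oncogene Myc fell (-4.19). Adjusted over the list alone, 4 rose and 1 fell, and the list was not called (camera adjusted p = 0.0542), though it was in 10 other settings. Dusp6 (1.05, adjusted p = 0.605) and Etv5 (-0.91, adjusted p = 0.499), both known ERK targets, did not pass.

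Of 21 trophectoderm genes, which mark the outer layer of the blastocyst, 3 fell with FGF4, and 7 when adjusted over the list alone (camera adjusted p = 0.000762, and adjusted p = 0.211 with an estimated correlation). They were the water channel Aqp3 (-3.63), the tight junction gene Cldn4 (-2.25) and Sfn (-1.79), while Cdx2 varied between libraries (-2.89, adjusted p = 0.239). The trophectoderm score per ICM was 4.77 ± 0.46 in DMSO and 3.72 ± 0.65 with FGF4 (difference -1.06, exact permutation test, adjusted p = 0.0437), a call that was lost in 9 of 13 runs that left out 1 library. Of 35 lysosome and autophagy genes 5 fell, and 7 when adjusted over the list alone, with Psap (-1.17), Ctsd (-1.17), Npc2 (-1.64) and Grn (-1.62) among them. Their camera adjusted p was 0.00811, and adjusted p = 0.205 with an estimated correlation, and the list was not called with the trophectoderm score as a covariate. Khdc3, an oocyte-derived transcript, fell (-1.07), as 1 of 6 tested genes of its list and 2 when adjusted over the list alone (camera adjusted p = 0.0122, and adjusted p = 0.15 with an estimated correlation). The ATF4 and amino acid list, which holds targets of the stress-response factor ATF4, was called higher (camera adjusted p = 0.000859, and adjusted p = 0.15 with an estimated correlation). Its members Asns (1.95) and Wars (0.90) rose out of 29, and 2 when adjusted over the list alone. The list of sterol and lipid synthesis genes was called lower (camera adjusted p = 0.00531, and adjusted p = 0.252 with an estimated correlation), with 0 of 30 members past the threshold and 5 lower when adjusted over the list alone.

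Among the genes of the rule outside the called lists, the largest rises besides Dusp4 (3.90) were in Flrt3 (6.48), a membrane protein that binds FGF receptors, Stbd1 (4.84), Shisal2b (4.65) and Foxq1 (3.64). Bcl3 was listed at 0 in all 8 FGF4 libraries and averaged 16.4 ± 4.56 TPM in DMSO (adjusted p = 0.00102). Etfbl (-5.76), Ube2h (-3.95) and Bcl2l14 (-3.68) fell. Across all genes 118 rose and 176 fell, out of 294 past the threshold. With the trophectoderm score as a covariate 36 genes were past the threshold, without Nanog, Gata4, Sox17, Klf2 and Spry4, with the estimated read number as a covariate 109, also without Nanog, Gata4, Sox17 and Spry4, and with library weights 1074. The trophectoderm score was itself lower with FGF4, so that covariate can also take away part of the FGF4 effect. Leaving out DMSO replicate 3, 6 or 7 gave 177, 144 and 114, and in the 13 runs that left out 1 library the calls of Serpinh1, Asns, Bcl2l14, Sox17, Lama1, Myc, P4ha1 and Cldn4 were lost in 7 to 10.

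**Figure D2:**
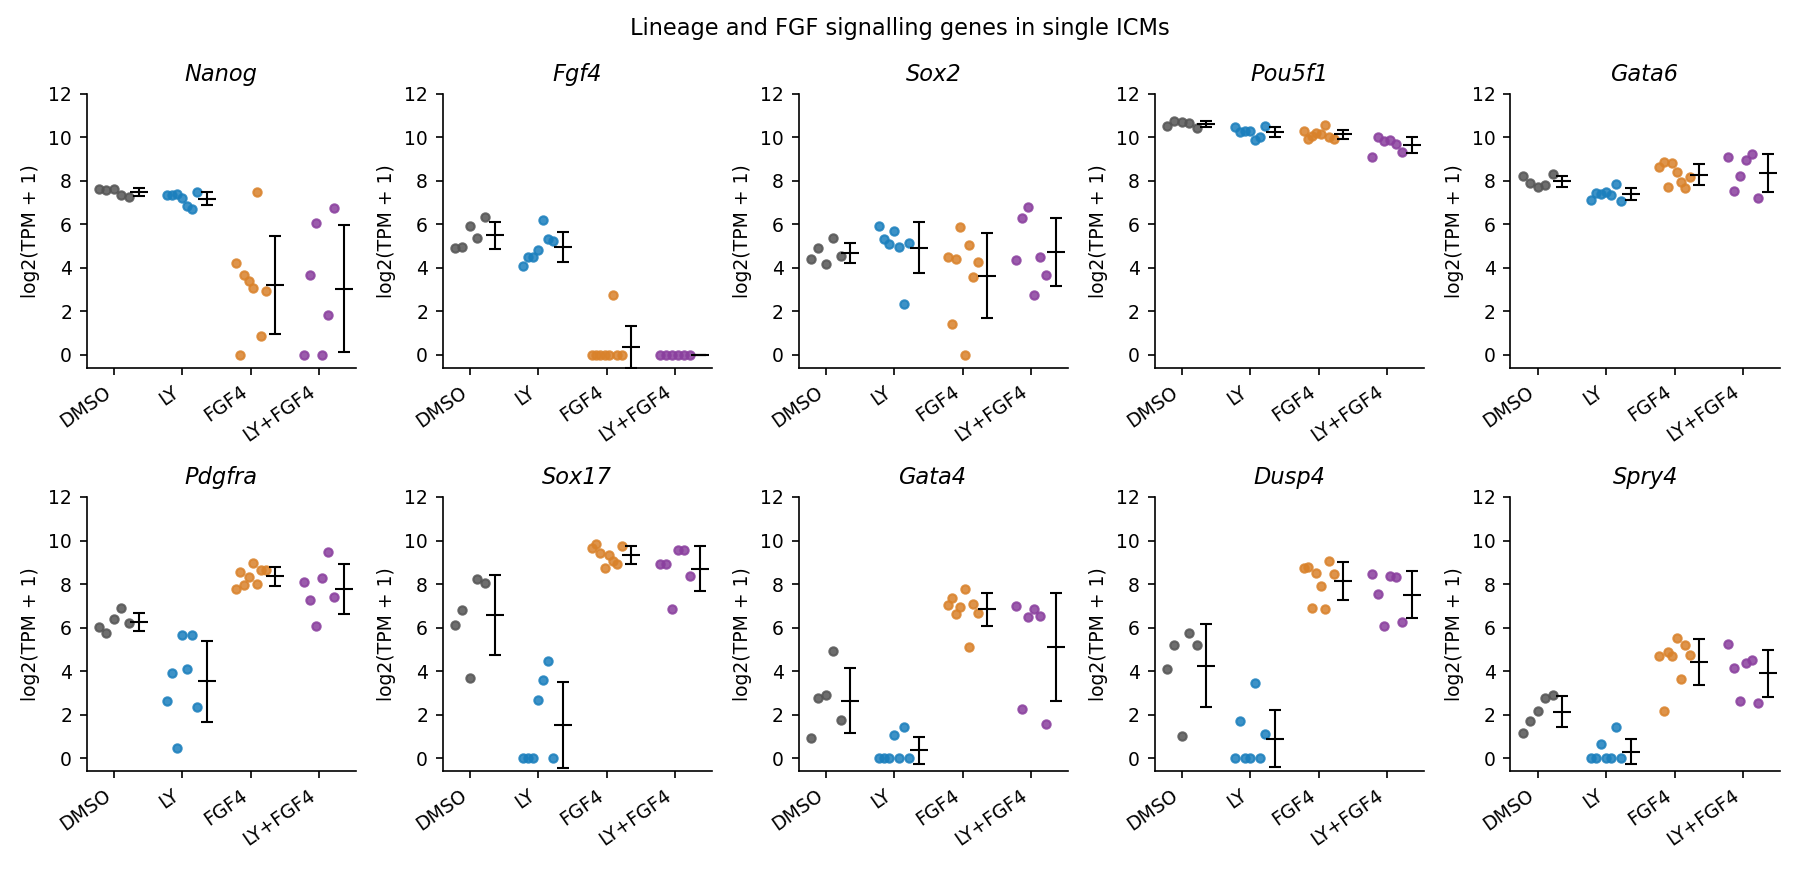
log2(TPM + 1) of 10 lineage and FGF signalling genes in each of the 26 ICMs, 1 point per library, with mean ± SD beside the points. Fgf4 lies at 0 in 7 of 8 FGF4 and 6 of 6 LY+FGF4 libraries, and Sox17 at 0 in 4 of 7 LY libraries.

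LY was compared with DMSO to ask what this inhibitor does to gene expression in the ICM. PI3K activity was not measured, so effects of LY are not shown to run through PI3K. ICMs cultured with LY had less primitive endoderm transcript and less transcript of amino acid and stress-response genes, while Nanog averaged 146 ± 27.9 TPM with LY and 178 ± 20.8 in DMSO. Sox17 averaged 5.35 ± 8.09 TPM (SD, n = 7), with 4 of 7 libraries at 0, against 151 ± 125 TPM (n = 5) in DMSO. Pdgfra averaged 19.7 ± 20.8 TPM against 78.3 ± 25 in DMSO. Nupr1, a stress-response gene downstream of ATF4, averaged 4.26 ± 9.59 TPM, with 5 of 7 libraries at 0, against 110 ± 82.4 TPM. Ftl1 and Fth1, which encode the ferritin chains that store iron, averaged 4293 ± 1277 and 2346 ± 926 TPM with LY against 1725 ± 364 and 1001 ± 238 TPM in DMSO.

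Of 29 ATF4 and amino acid genes, 6 fell and none rose, and 16 fell when adjusted over the list alone (camera adjusted p = 3.58e-19, and adjusted p = 0.000211 with an estimated correlation). They were Nupr1 (-5.43, adjusted p = 0.00127), Trib3 (-3.86), Chac1, which degrades glutathione (-3.72), Mthfd2, a mitochondrial folate enzyme (-3.20), Psat1, of serine synthesis (-1.66), and the amino acid transporter subunit Slc3a2 (-1.02). Of 30 sterol and lipid synthesis genes 1 fell, Fdps of the mevalonate pathway (-2.01, adjusted p = 0.0353), and 6 when adjusted over the list alone (camera adjusted p = 3.22e-12, and adjusted p = 0.00933 with an estimated correlation).

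Of 29 primitive endoderm genes 3 fell, Sox17 (-5.05, adjusted p = 0.000884), Pdgfra (-2.71, adjusted p = 0.0455) and the matrix protein gene Sparc (-2.13, adjusted p = 0.0259). Adjusted over the list alone 7 fell and 1 rose (camera adjusted p = 1.79e-05, and adjusted p = 0.189 with an estimated correlation). Gata4 was at 0 in 5 of 7 LY libraries but did not pass the test (-2.29, adjusted p = 0.321), and Gata6 averaged 168 ± 32 TPM against 253 ± 46.4 in DMSO (-0.59, adjusted p = 0.613). The primitive endoderm score ranged from 2.29 to 3.24 with LY and from 3.22 to 4.64 in DMSO (difference -1.13, exact permutation test, adjusted p = 0.0105). Epiblast genes did not pass the test as a list (camera adjusted p = 0.133, and 0 of 14 past the threshold), although 12 of 14 were lower (median -0.41) and the list was called lower in 2 other settings, with the estimated read number as a covariate (camera adjusted p = 0.0391) and without LY replicate 8. Nanog (-0.31, adjusted p = 0.985), Sox2 (0.26, adjusted p = 0.985), Fgf4 (-0.55, adjusted p = 0.887) and Pou5f1 (-0.36, adjusted p = 0.463) gave no call. Among FGF/ERK targets Dusp4 fell (-3.36, adjusted p = 0.0228), while Spry4 (-1.84, adjusted p = 0.225), Dusp6 (-0.76) and Etv5 (-0.85) did not pass, nor did Cdx2 (-3.02, adjusted p = 0.455).

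3 other lists were called with LY, each with 0 members past the threshold. p53 targets were higher (camera adjusted p = 4.18e-05, and adjusted p = 0.189 with an estimated correlation), with 1 of 22 higher when adjusted over the list alone. Ribosome biogenesis genes were lower (camera adjusted p = 0.000845, and adjusted p = 0.189 with an estimated correlation), and so were S phase genes (camera adjusted p = 0.00097, and adjusted p = 0.298 with an estimated correlation). For these lists 0 members passed when adjusted over the list alone. With fry, p53 targets (adjusted p = 0.185) and S phase genes (adjusted p = 0.0764) gave no call. Outside the called lists, Aldh1b1, a mitochondrial aldehyde dehydrogenase (-4.93), Lmo2 (-3.58) and Saa3 (-3.71) fell, and Slc5a11 was listed at 0 in all 7 LY libraries against 15.1 ± 8.84 TPM in DMSO. The rises were smaller, in Wipi2, which acts in autophagy (1.64), Arl6ip1 (1.37), the centromeric histone gene Cenpa (1.35), Ftl1 (1.28), Fth1 (1.18), Rogdi (1.05), Aplp2 (1.00) and Mlf2 (0.71). Ftl1 and Fth1 have pseudogene copies, and how reads were shared between copies is not known.

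Across all genes 9 rose and 36 fell, out of 45 past the threshold. Library weights gave 496, the number of genes listed as a covariate 19, the Y-linked genes as a covariate 29, the replicate block 5, and the estimated read number as a covariate 6, where 19 of 22 named genes, including Sox17, Pdgfra, Sparc, Nupr1, Chac1 and Psat1, lost their calls. Leaving out DMSO replicate 3, 6, 8 or 9 gave 20, 27, 29 and 16 genes, the calls of Pdgfra, Fdps, Saa3, Mlf2, Rogdi and Aplp2 were lost in 7 to 10 of the 12 runs that left out 1 library and that of Sparc in 5, and 17 of 100 splits of the libraries called as many as 6 lists.

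LY+FGF4 was compared with FGF4 to ask what the inhibitor does when FGF4 is supplied. With FGF4 present, ICMs treated with LY had less transcript of ATF4 and amino acid genes and of sterol synthesis genes, and no transcription factor of primitive endoderm changed past the threshold. These factors are not shown to be unaffected. Gata4 was at 3.77 and 1.97 TPM in LY+FGF4 replicates 3 and 8, below the lowest FGF4 library at 34.07 TPM. In replicates 2, 5, 6 and 7 it was at 87.5 to 125 TPM. Chac1 averaged 52.9 ± 27.4 TPM (SD, n = 8) with FGF4 and was listed at 0 in all 6 LY+FGF4 libraries. Nupr1 averaged 187 ± 63.6 TPM with FGF4 and 6.04 ± 10 TPM (n = 6) with both. Sox17 averaged 667 ± 179 TPM with FGF4 and 493 ± 253 TPM with both, and Lama1, a laminin chain of the basement membrane, 111 ± 81.1 and 8.84 ± 11.9 TPM.

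All 29 ATF4 and amino acid genes had negative log2 fold changes, and 17 of them fell, or 24 when adjusted over the list alone (camera adjusted p = 1.32e-20, and adjusted p = 0.000127 with an estimated correlation). They included Nupr1 (-6.08), Trib3 (-4.86), the mTORC1 inhibitor gene Ddit4 (-3.92), Mthfd2 (-2.82) and the seryl-tRNA synthetase gene Sars (-1.56). Of 30 sterol and lipid synthesis genes 8 fell, and 17 when adjusted over the list alone (camera adjusted p = 7.92e-09, and adjusted p = 0.0405 with an estimated correlation). Examples are Fdft1 (-2.95), the desaturases Scd2 (-2.89) and Scd1 (-2.29), and Insig1 (-2.15).

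Of 29 primitive endoderm genes 4 fell, and 8 when adjusted over the list alone (camera adjusted p = 0.0232, and adjusted p = 0.754 with an estimated correlation). The list was called in 24 of 32 settings, and not without FGF4 replicate 2 or LY+FGF4 replicate 3, 5 or 8, nor without the 6 libraries under 9000 genes (camera adjusted p = 0.911), where the 4 genes lost their calls as well. The 4 were the laminin genes Lama1 (-3.97) and Lamb1 (-3.15), Cubn, an endocytic receptor (-2.01), and Srgn, a proteoglycan listed at 0 in all 6 LY+FGF4 libraries. The transcription factors of the lineage gave no call, with Sox17 at -0.63 (adjusted p = 0.67), Gata4 at -1.72 (adjusted p = 0.212) and Gata6 at 0.10 (adjusted p = 0.894), and Pdgfra gave -0.59 (adjusted p = 0.62). The primitive endoderm score was 4.43 ± 0.81 with both and 5.52 ± 0.67 with FGF4 (difference -1.09, exact permutation test, adjusted p = 0.0533). Nanog (-0.16, adjusted p = 0.952), Sox2 (1.09, adjusted p = 0.46), Fgf4, Dusp4 (-0.65, adjusted p = 0.635), Dusp6 (0.75), Spry4 (-0.53), Etv5 (1.10) and Cdx2 (-0.89) also gave no call, while Pou5f1 fell (-0.50, adjusted p = 0.0456), a call that was lost in 9 of 14 runs that left out 1 library. p53 targets were called higher as a list (camera adjusted p = 0.0286, and adjusted p = 0.754 with an estimated correlation) with 0 of 22 members past the threshold, over all genes or adjusted over the list alone. The call was lost in 6 of those 14 runs and without the 6 libraries under 9000 genes, where the mean of the list turned to -0.31. Fry did not call that list in the main fit (adjusted p = 0.659).

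Outside the called lists, the actin-capping gene Capg (-5.13), Rpap2 (-4.75) and the transporter gene Slc16a5 (-4.45) fell. Wdr25 (-5.33), which overlaps Wars on chromosome 12, and the small nucleolar RNA Snord17 (-4.87) fell as well, with values that are uncertain because of the overlap and the short transcript. The ubiquitin ligase adaptor Fbxo2 rose (4.61, adjusted p = 0.000551), from 13.8 ± 14.4 TPM to 222 ± 158 TPM. Nr4a1 (3.07), Pttg1 (2.84), Tent5c (2.79), the growth factor gene Nrg1 (2.74), Ube2h (2.69), Rbmxl2 (2.54) and the cleavage-stage gene Klf17 (2.52) also rose. All genes from Nr4a1 to Klf17 lost their calls without the 6 libraries under 9000 genes, where the direction of Tent5c reversed. Rpap2 and Snord17 lost theirs there as well.

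Across all genes 87 rose and 340 fell, out of 427 past the threshold, while the median log2 fold change of all genes was -0.24 and the LY+FGF4 libraries listed the fewest genes. In simulated data with each group's own spread 71 calls were false, 57.7% of those made there, which is not the false share of these 427. That simulation counts no false calls from lost transcripts. Library weights gave 111 genes, and fitting only the groups compared gave fewer than that. The number of genes listed as a covariate gave 187, more of them higher than lower. With it 16 of the 27 genes of the rule that had been called lost their calls, such as Lama1, Cubn, Srgn, Scd1, Fdft1 and Pou5f1. Quantile normalization gave 128 higher and 190 lower genes. Leaving out the 6 libraries under 9000 genes gave 169, and leaving out FGF4 replicate 7 gave 283. Klf17, Lamb1 and Nr4a1 lost their calls in 10 to 12 of 14 runs that left out 1 library, and 25 of 100 splits called as many lists.

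**Figure D3:**
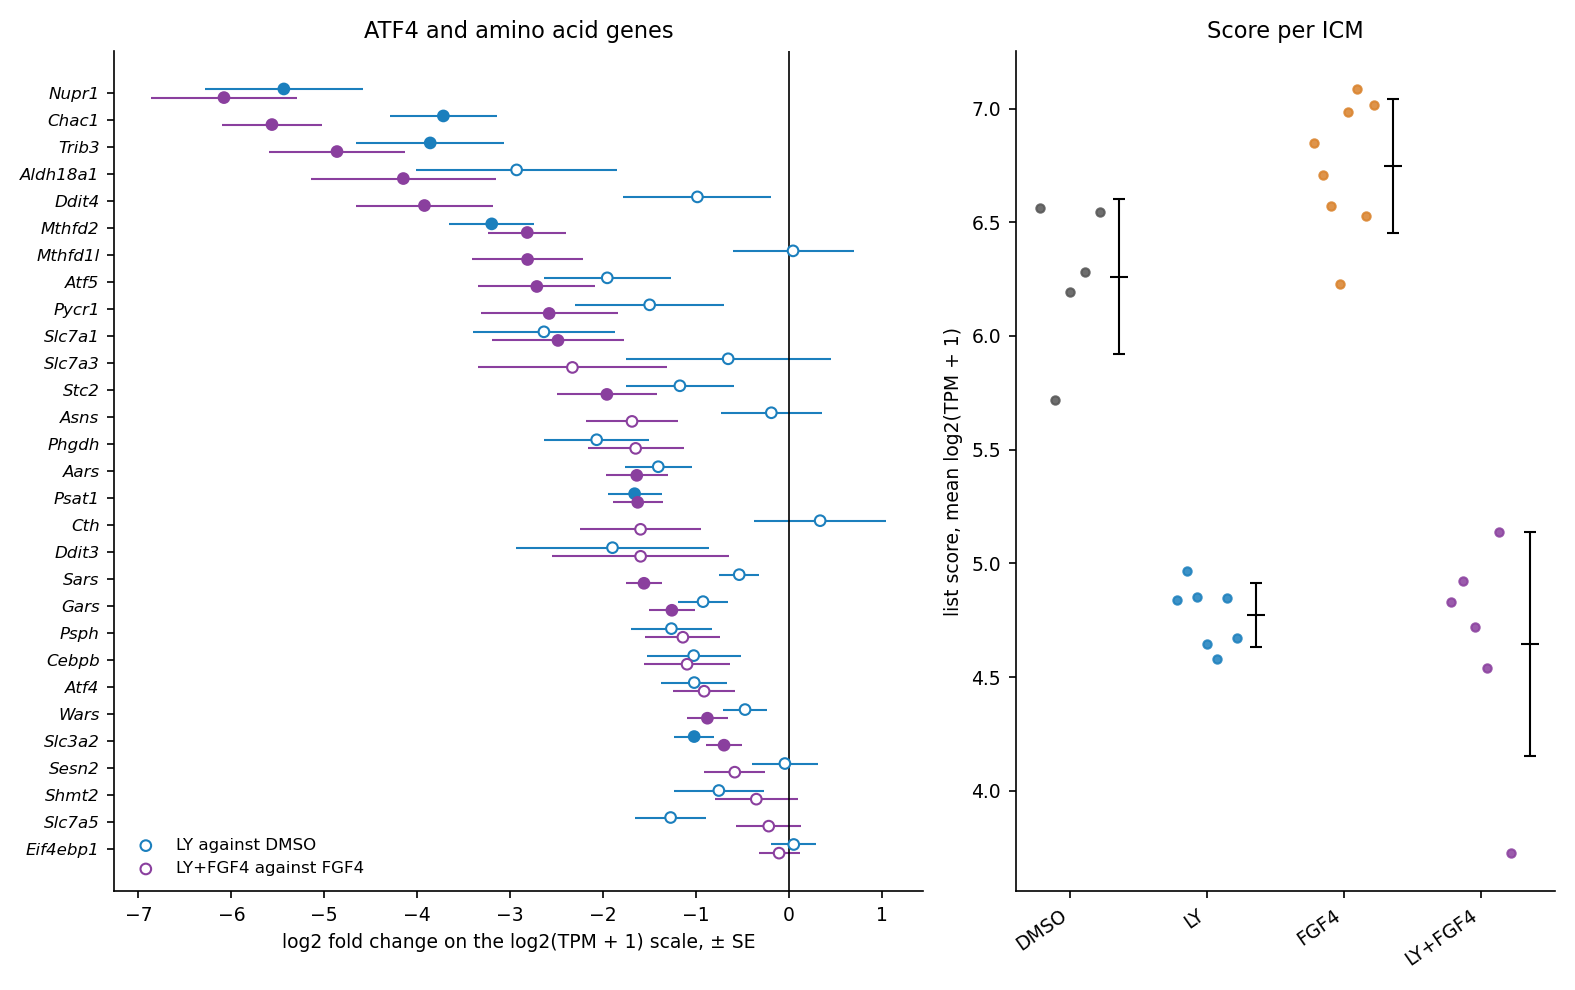
Left, log2 fold change ± SE of the 29 ATF4 and amino acid genes for LY against DMSO and for LY+FGF4 against FGF4, with filled points where the adjusted p was under 0.05. Right, the mean log2(TPM + 1) of these genes per ICM with mean ± SD; all 7 LY libraries lie below the 5 DMSO libraries, and all 6 LY+FGF4 libraries below the 8 FGF4 libraries.

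LY+FGF4 was compared with LY to ask whether FGF4 acts on the ICM when the inhibitor is there. With LY present, FGF4 changed genes of both lineages. Sox17 averaged 5.35 ± 8.09 TPM (SD, n = 7) with LY and 493 ± 253 TPM (n = 6) with both, Pdgfra 19.7 ± 20.8 and 282 ± 232 TPM, and Dusp4 1.9 ± 3.61 and 221 ± 129 TPM. In these 3 genes every LY+FGF4 library was above every LY library. Nanog averaged 146 ± 27.9 TPM with LY and 30.6 ± 44 TPM with both, and Fgf4 averaged 33.4 ± 19.3 TPM with LY and was listed at 0 in 6 of 6 LY+FGF4 libraries.

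Of 29 primitive endoderm genes 10 rose and none fell, and 13 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.95e-12, and adjusted p = 0.0278 with an estimated correlation). They included Sox17 (7.18, adjusted p = 3.24e-07), Gata4 (4.75, adjusted p = 0.000596), Pdgfra (4.23), Fgfr2, an FGF receptor (4.57), Sparc (2.91), and Gata6 (0.98, adjusted p = 0.0365). Of 22 FGF/ERK targets 5 rose, Dusp4 (6.61), Spry4 (3.61), Etv4 (2.87), Spred1 (2.27) and Phlda1 (2.24), and Lif, a cytokine gene, fell (-2.43). Adjusted over the list alone 7 rose and 1 fell (camera adjusted p = 0.000228, and adjusted p = 0.0173 with an estimated correlation), and the list was not called among genes of mean TPM of at least 30. Dusp6 (2.56, adjusted p = 0.0629) and Etv5 (1.04, adjusted p = 0.307) did not pass.

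Of 14 epiblast genes 6 fell, and 8 when adjusted over the list alone (camera adjusted p = 0.000305, and adjusted p = 0.0969 with an estimated correlation). Besides Fgf4 they were Klf2 (-4.44), Nanog (-4.13, adjusted p = 0.00978), Tdh, a threonine-degrading enzyme (-3.98), Gdf3 (-3.12) and Tdgf1 (-3.06). Sox2 did not pass (-0.20, adjusted p = 0.922), nor did Cdx2 (-0.76, adjusted p = 0.768), and Pou5f1 fell (-0.61, adjusted p = 0.0127). The trophectoderm score differed by -0.68 (exact permutation test, adjusted p = 0.154). Basement membrane genes were called higher as a list (camera adjusted p = 0.00223, and adjusted p = 0.293 with an estimated correlation). Of 24, 5 rose and 2 fell, and 7 rose and 2 fell when adjusted over the list alone, with Serpinh1 (4.98), Col4a1 (2.24) and the integrin gene Itga6 (1.99) among those that rose. Sterol and lipid synthesis genes were lower (camera adjusted p = 0.00994, and adjusted p = 0.358 with an estimated correlation), with 5 of 30 that fell and 6 when adjusted over the list alone, such as Msmo1 (-3.85), Insig1 (-1.97) and Scd2 (-1.83), and that list was not called without the 6 libraries under 9000 genes (camera adjusted p = 0.106). Of 35 lysosome and autophagy genes 6 fell, and 8 when adjusted over the list alone (camera adjusted p = 0.0237, and adjusted p = 0.334 with an estimated correlation), among them Uvrag (-2.67), Npc2 (-1.93), Psap (-1.07) and Atp6v0d1 (-0.86), and the list lost its call without LY replicate 3, without LY+FGF4 replicate 7 and with the trophectoderm score as a covariate. Without the 6 libraries under 9000 genes Uvrag and Atp6v0d1 lost their calls, and the direction of Uvrag reversed. Hippo/YAP targets were called higher (camera adjusted p = 0.0371, and adjusted p = 0.334 with an estimated correlation), with Nt5e (2.80) the 1 of 10 that rose and 3 when adjusted over the list alone. The list lost its call in 7 of 13 runs that left out 1 library and Nt5e in 9. With fry, neither Hippo/YAP targets (adjusted p = 0.145) nor basement membrane genes (adjusted p = 0.084) were called.

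Outside the called lists, Lmo2 (4.42) and Nup62cl (4.21) rose, and Pramel5 (-4.96), Ly6e (-4.74), Mboat1 (-4.73), the kinase gene Sgk1 (-4.67), Wdr25 (-4.48) and Snord17 (-4.44) fell. Across all genes 216 rose and 542 fell, out of 758 past the threshold, with a median log2 fold change of -0.24 over all genes. In simulated data with each group's own spread 53 calls were false, 52.5% of those made there, which is not the false share of these 758. That simulation counts no false calls from lost transcripts. The number of genes listed as a covariate gave 108, without 21 of the 36 genes of the rule that had been called, such as Nanog, Tdh, Pou5f1, Gata6, Col4a1 and Insig1, library weights 356, the trophectoderm score as a covariate 377, also without Nanog, Pou5f1 and Gata6, and quantile normalization 271 higher and 409 lower genes, Gata6 and Etv4 lost their calls in 9 and 7 of 13 runs that left out 1 library, and 15 of 100 splits called as many lists.

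LY+FGF4 was also compared with DMSO, for the effect of both agents together. Epiblast, sterol synthesis and ATF4 genes were lower in the ICMs that had both, and some primitive endoderm and ERK target genes were higher. Insig1, a regulator of sterol synthesis, averaged 380 ± 99.5 TPM (SD, n = 5) in DMSO and 36.7 ± 16.6 TPM (n = 6) with both. Tdgf1, a co-receptor of the epiblast, averaged 209 ± 76.3 and 20.1 ± 30 TPM, and Dusp4 28.4 ± 20 and 221 ± 129 TPM.

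Of 30 sterol and lipid synthesis genes 16 fell, and 24 when adjusted over the list alone (camera adjusted p = 7.02e-11), such as Scd2 (-3.58), Insig1 (-3.42), Scd1 (-3.39) and Fdps (-3.10). Of 29 ATF4 and amino acid genes 10 fell, and 17 when adjusted over the list alone (camera adjusted p = 2.88e-06), with Nupr1 (-5.05), Psat1 (-1.88) and Sars (-1.31) among them and Chac1 listed at 0. Of 14 epiblast genes 9 fell, and 10 when adjusted over the list alone (camera adjusted p = 1.03e-05), among them Tdgf1 (-4.74), Nanog (-4.44, adjusted p = 0.00783), Tdh (-4.07) and Gdf3 (-3.46), with Fgf4 listed at 0 in LY+FGF4. Of 22 FGF/ERK targets 3 rose, Dusp4 (3.25), Spred1 (2.35) and Phlda1 (1.51), and 4 when adjusted over the list alone (camera adjusted p = 0.00137), with no call among genes of mean TPM of at least 30. For each of these 4 lists the adjusted p was 0.0258 with an estimated correlation.

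Of 29 primitive endoderm genes 5 rose, Dkk1 (3.01), Fgfr2 (2.64), Lrp2 (2.11), Col4a1 (1.75) and Lamc1 (1.60), and 7 when adjusted over the list alone (camera adjusted p = 0.000462, and adjusted p = 0.294 with an estimated correlation). The primitive endoderm score differed by 0.54 and did not pass (exact permutation test, adjusted p = 0.283). With the trophectoderm score as a covariate the list was not called (camera adjusted p = 0.127), and Dkk1, Fgfr2, Col4a1 and Lamc1 lost their calls. Sox17 (2.13, adjusted p = 0.077), Gata4 (2.46, adjusted p = 0.0646), Pdgfra (1.52, adjusted p = 0.137) and Gata6 (0.39, adjusted p = 0.451) did not pass, while Gata4, Sox17 and Gata6 passed in 8, 2 and 1 of the other settings. Of 24 basement membrane genes 3 rose, with P4ha1 (1.20) among them, and Fbln1 fell (-3.31), and 4 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.00338, and adjusted p = 0.294 with an estimated correlation), a call that was lost with the same covariate. G2/M genes were called higher as a list (camera adjusted p = 0.0106, and adjusted p = 0.521 with an estimated correlation). Of 33, Bub3 (1.12), of the spindle checkpoint, and Top2a (1.39) rose, and 3 fell, including Cdca3 (-1.80) and Birc5 (-0.75), and 6 rose and 3 fell when adjusted over the list alone. Without the 6 libraries under 9000 genes the mean of that list turned to -0.28, and the call was also lost with quantile normalization, library weights and the number of genes listed as a covariate. With fry, primitive endoderm (adjusted p = 0.204), basement membrane (adjusted p = 0.204) and G2/M genes (adjusted p = 0.5) were not called. Pou5f1 fell (-0.97, adjusted p = 0.000416). Sox2 (0.06), Cdx2 (-3.79, adjusted p = 0.066), Spry4 (1.77, adjusted p = 0.0661), Dusp6 (1.79) and Etv5 (0.19) gave no call, and the trophectoderm score differed by -1.11 (exact permutation test, adjusted p = 0.0935).

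Aldh1b1, Etfbl, Pdpn and Slc4a5 were listed at 0 in all 6 LY+FGF4 libraries and averaged 53.6 ± 23.5, 235 ± 153, 67 ± 37.6 and 53.5 ± 39.1 TPM in DMSO, and Mir5625, a microRNA locus with an uncertain TPM, was also listed at 0. Capg (-5.84) and Wdr25 (-5.77) fell, and Pdp1 (3.31), Nectin3 (3.30), Pth1r (3.27), Pmaip1, a pro-apoptotic gene (3.10), and Nrg1 (2.96) rose. Across all genes 264 rose and 879 fell, out of 1143 past the threshold, with a median log2 fold change of -0.37 over all genes. In simulated data with each group's own spread 18 calls were false, 32.7% of those made there, which is not the false share of these 1143. That simulation counts no false calls from lost transcripts. With the number of genes listed as a covariate 75 genes were past the threshold, 46 higher and 29 lower, without 30 of the 40 genes of the rule that had been called, such as Nanog, Tdgf1, Tdh, Dusp4, Nupr1, Sars, Scd1, Fdps and Pou5f1, the trophectoderm score as a covariate gave 370, also without Nanog and Dusp4, quantile normalization gave 459 higher and 652 lower genes, leaving out DMSO replicate 3, 6, 7 or 8 or the libraries under 9000 genes gave 760, 671, 726, 756 and 601, P4ha1, Pth1r and Spred1 lost their calls in 7 to 9 of 11 runs that left out 1 library, and 18 of 100 splits called as many lists.

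The interaction asked whether the LY effect differed with and without FGF4. 6 genes were past the threshold and 726 had an unadjusted p under 0.05. Rcc2, a gene of chromosome segregation, averaged 383 ± 143 TPM in DMSO (n = 5), 52.8 ± 28.8 with LY (n = 7), 50.4 ± 24.2 with FGF4 (n = 8) and 108 ± 90.3 with both (n = 6), so each agent alone gave a low level (interaction 3.87, limma adjusted p = 0.00483). Ybx3, a cold shock domain gene, averaged 381 ± 123, 197 ± 72.8, 96.5 ± 27.5 and 315 ± 87.2 TPM in the same order (2.68, adjusted p = 0.000455). Wac averaged 307 ± 47.9, 328 ± 91.4, 280 ± 104 and 1113 ± 391 TPM (1.96, adjusted p = 0.0213). Kptn (-4.12), N4bp2 (-4.55) and Serhl (-4.34) averaged 1.47 ± 2.28, 3.3 ± 2.47 and 0.36 ± 0.882 TPM with both agents and at least 15.2 TPM in each of the other groups. The call of Kptn was lost in 19 of 26 runs that left out 1 library, that of N4bp2 in 11, and those of Serhl and Wac in 4 each. Kptn and N4bp2 also lost their calls with the number of genes listed as a covariate. Kptn, Serhl and Wac lost theirs without the 6 libraries under 9000 genes. Sox17 had an interaction of 4.42 that did not pass the test (adjusted p = 0.143), so its loss with LY alone is not shown to differ from that with FGF4, though it passed in 2 other settings. Dusp4 (2.72, adjusted p = 0.581), Pdgfra (2.12, adjusted p = 0.696), Cdx2 (2.13), Etv5 (1.95), Dusp6 (1.51), Spry4 (1.31), Sox2 (0.83), Gata6 (0.68), Gata4 (0.57), Nanog (0.15), Pou5f1 (-0.14) and Fgf4, at 0 in the LY+FGF4 libraries, gave no call. None of the 26 lists was called, with a smallest adjusted p of 0.178. Leaving out DMSO replicate 3 or 8 gave 3 genes, LY replicate 4 or 8 gave 2 genes, LY+FGF4 replicate 3 gave 11, and leaving out the libraries under 9000 genes gave 28.

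The balance of the lineages in each ICM was summarised by the epiblast score minus the primitive endoderm score. It was 2.35 ± 0.35 in DMSO (n = 5), 2.81 ± 0.74 with LY (n = 7), -1.22 ± 1.21 with FGF4 (n = 8) and -0.59 ± 1.13 with both (n = 6). The FGF4 libraries ranged from -2.61 to 0.77. With both agents, the balance was 0.0055, 0.23 and 0.85 in replicates 3, 5 and 8, and -2.06, -1.61 and -0.96 in replicates 2, 6 and 7. It was lower with FGF4 than in DMSO and lower in LY+FGF4 than with LY, with no overlap between libraries (exact permutation tests, adjusted p = 0.00194 for each, from the smallest p they can give). LY+FGF4 was lower than DMSO as well (exact permutation test, adjusted p = 0.00722). LY did not move it past the threshold without FGF4 (exact permutation test, adjusted p = 0.306) or with it (adjusted p = 0.333, exact permutation test). The epiblast score differed by -1.94 between FGF4 and DMSO and by -1.73 between LY+FGF4 and LY (exact permutation tests, adjusted p = 0.00486 for each), and by -0.67 between LY and DMSO (exact permutation test, adjusted p = 0.109). Within groups, the epiblast and primitive endoderm scores were not related past the threshold. In the 3 groups with at least 6 ICMs, r was -0.0023 with LY, -0.238 with both and -0.598 with FGF4 (exact permutation test, p = 0.136, adjusted p = 0.407). In FGF4, rho was -0.429 (exact permutation test, p = 0.299), and r was -0.587 without the 2 ICMs farthest from the median. Without the 2 farthest of each group, r was 0.82 with LY and 0.334 with both, so in these groups r rested on 2 ICMs.

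**Figure D4:**
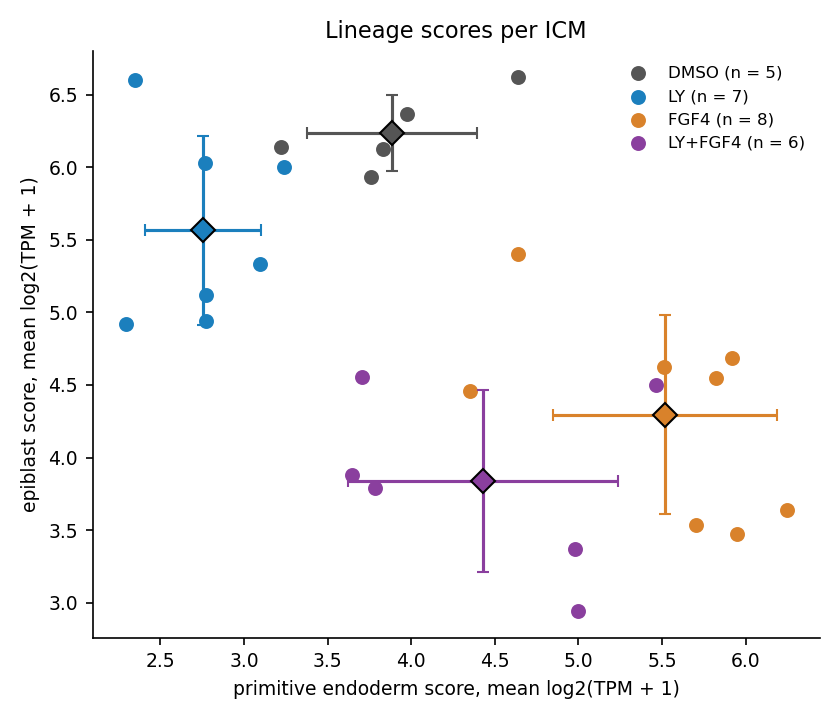
Epiblast score against primitive endoderm score (each the mean log2(TPM + 1) of its list) in single ICMs, 1 circle per library, with diamonds and bars for the mean ± SD of each group. FGF4 and LY+FGF4 libraries have low epiblast scores, and all 7 LY libraries have primitive endoderm scores of 3.24 or less.

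The effects of each agent were compared across genes between the 2 backgrounds, in contrasts that share no library. Across 12034 genes, which are not independent replicates, the LY effects with and without FGF4 had r = 0.33 and rho = 0.31. The highest r of 99 regroupings was 0.125 (permutation test, p = 0.01, the smallest they can give). 15 genes fell with LY in both backgrounds, where 1.02 were expected by chance, 6 rose in both, where 0.0651 were expected, and 0 moved in opposite directions. The FGF4 effects with and without LY had r = 0.46 and rho = 0.43, with 0.207 as the highest r of 99 regroupings (permutation test, p = 0.01, the smallest they can give). 82 genes fell in both backgrounds and 54 rose in both, where 7.93 and 2.12 were expected, and 0 moved in opposite directions. LY and FGF4 effects against the shared DMSO libraries had r = 0.286, below the r of 0.456 that the shared controls gave in 100 simulated draws without any effect. Their covariance was 0.196, against 0.152 in the draws, and with the DMSO libraries split between the contrasts the median r of 20 splits was 0.0625 (-0.00911 to 0.108). 7 genes fell with both agents, 0 rose with both and 3 moved in opposite directions. For contrasts without shared libraries 0.527, 0.0883 and 0.485 would be expected. The shared DMSO libraries alter these numbers, and the numbers expected with shared libraries were not computed, so no excess is shown.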

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

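The tests on read number, on abundant genes, on the ATF4 score per library and on a mixture of ICMs were chosen, or given their final bounds, only after the result was seen.

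5 values lay far from the rest of their group, by the gap to the nearest library over the range of the group. They were found in 80 groups of 5 to 8 libraries, where 4 are expected by chance. In FGF4 replicate 2, Dusp6 was 0 on the log2(TPM + 1) scale. In DMSO replicate 8, Etv5 was 6.98. In FGF4 replicate 6, the embryo's own Fgf4 was 2.748, against 0 in the other FGF4 libraries, and Gata4 was 5.13. In LY replicate 7, Sox2 was 2.35.

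6 genes had an LY effect that differed with and without FGF4 by the interaction test. The log2 interaction was -4.12 for Kptn, -4.55 for N4bp2, 3.87 for Rcc2, -4.34 for Serhl, 1.96 for Wac and 2.68 for Ybx3. 1 of 100 splits of the libraries, the real one, gave as many, and the highest other split gave 1. These splits moved all 26 libraries between the groups, so they also took away the effects of each agent alone. Chance is therefore not excluded for this number. With each group's own spread, simulated data gave 1 false interaction call with changed genes drawn from all tested genes. They gave 9 with changed genes of mean TPM of at least 30.

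FGF4 replicate 6 listed Nanog at 176 TPM, where DMSO averaged 178 TPM and no other FGF4 library exceeded 17.4 TPM, and it also listed Cdx2 at 282 TPM and Etv5 at 518 TPM, above every DMSO and other FGF4 library, with a trophectoderm score of 5.02 against 2.93 to 4.16 in the other FGF4 libraries. An untreated ICM under the FGF4 label is argued against, since its score over the genes that changed between LY+FGF4 and LY was 1.09, above the DMSO range of -0.11 to 0.32, with 1.93 to 2.84 in the other FGF4 libraries. A mixture of RNA from a treated and an untreated ICM stays open, since Nanog would need a DMSO share of 98.96%, the other 81 genes lower in both FGF4 comparisons gave quartiles of 19.4 and 64.3%, 3 of them were as high as Nanog, and Fgf4 gave 11.99%, while Cdx2 and Etv5 lay above what the measured levels of the 2 groups would mix to. The first bound asked only that Nanog lie outside these quartiles and was passed, but it was replaced after that result, because a share of genes lies above a quartile by construction and Nanog was picked for its level. RNA of outer cells left on this ICM and a weaker response of it were not tested, and no biological explanation was tested.

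The LY+FGF4 libraries listed fewer genes than those of DMSO, and 879 of the 1143 genes past the threshold against DMSO were lower, or 76.9%. A smaller number of reads as the whole cause is argued against, since after thinning to a common read number the highest LY+FGF4 library listed 9247 genes and the lowest DMSO library 9963 (exact permutation test, p = 0.00216, the smallest it can give). Random loss of transcripts stays open, since the 62.3% of lower genes with an LY+FGF4 library at 0 decide nothing, as lower genes are picked for low values in these libraries, and since 65.0% of the changed genes with mean TPM of at least 100 were lower (exact 95% interval 60.3 to 69.5%), above the 40 to 60% that loss predicts but below the bound of 70% that would have excluded it, with a library at 0 for 23 of the 280 lower ones. That test first took genes by their mean in DMSO, which gave 75% (70.8 to 78.9%) and passed the bound, but it was replaced after this result because genes chosen for a high level in DMSO are more often lower elsewhere. Both intervals treat the changed genes as independent, though they share the same libraries, so the intervals are too narrow. The range of 40 to 60% was set by hand and not computed from a model of loss. Of 7255 genes at TPM of at least 1 in every DMSO and LY library, 1980 were at 0 in an LY+FGF4 library. Of these, 1107 were at 0 in exactly 1, 489 in 2, 230 in 3, 95 in 4, 50 in 5 and 9 in all 6. The numbers that random loss would give were not computed, so these counts decide nothing. The median log2 ratio of mean TPM, LY+FGF4 over DMSO, was -0.0222, against a median log2 fold change of -0.369. An effect of both agents on many genes and poorer libraries in this group cannot be told apart, because the low gene number goes with the group, and with that number as a covariate 75 genes were past the threshold.

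The ATF4 and amino acid list was lower with LY both without and with FGF4, in scores of 4.77 ± 0.14 with LY against 6.26 ± 0.34 in DMSO, and 4.65 ± 0.49 with both against 6.75 ± 0.29 with FGF4. Fewer genes listed in the LY libraries as the whole cause is argued against, since with that number as a covariate the larger adjusted p of the list was 3.14e-16. An unequal share of male and female embryos is argued against in the same way, with 2.57e-19 for the Y-linked genes as a covariate. Treatment with LY is a candidate explanation, since every library with LY scored below every library without it in each background, with exact permutation p of 0.00126 and 0.000333, the smallest these designs can give. That outcome was nearly implied by the list calls, already seen, and the labels name no batch that could be tested.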

How the results depend on the processing

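The tests with the estimated read number, with thinned libraries, with mean TPM of at least 30, without the shallowest libraries and without the 6 libraries under 9000 genes were chosen only after the result was seen, and all other alternatives before the data were examined. The ATF4 and sterol lists were called lower under each setting that tested lists, for LY against DMSO (highest adjusted p = 5.28e-13 and 1.18e-09) and for LY+FGF4 against FGF4 (4.01e-14 and 2.17e-05). Gene counts depended on the setting in every comparison. Of the named genes, 9 of 22, 16 of 34, 19 of 27, 29 of 36, 28 of 40 and 2 of 6 stayed past the threshold whichever library was left out, with none reversed. Under all other alternatives chosen beforehand, apart from the block and the Wilcoxon test, 9, 5, 9, 13, 10 and 2 did, and under the later ones 3, 16, 12, 27, 21 and 3. With the trophectoderm score as a covariate 29 of the 34 for FGF4 against DMSO lost their call, including Nanog, Gata4, Sox17, Klf2 and Spry4. That score was itself lower on average in both groups with FGF4. As a covariate it can therefore take away part of the FGF4 effect, and such losses do not show that these effects are absent. The comparisons are always in the order LY against DMSO, FGF4 against DMSO, LY+FGF4 against FGF4, against LY and against DMSO, and the interaction. Removing mitochondrially encoded genes was not run, since none matched. Where no cause is given, the cause was not tested. In simulated data with each group's own spread, 4-fold changes were found in 14 to 40 of 100 genes drawn from all tested genes. Among genes of mean TPM of at least 30 they were found in 36 to 72 of 100. Uncalled genes are therefore not shown to be unchanged.

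Library weights gave 496, 1074, 111 and 356 genes in the first 4 comparisons. Without trend and robust fitting the first 2 had 28 and 187. The number of genes listed as a covariate gave 19, 181, 187, 108 and 75, with 113 higher and 74 lower in the third, the reverse of the main balance of 87 and 340. The Y-linked genes as a covariate gave 29 for LY against DMSO and 438 for LY+FGF4 against LY, and the trophectoderm score gave 36, 377 and 370 for FGF4 against DMSO and LY+FGF4 against LY and DMSO. The replicate block gave 5, 41, 224 and 460 in the first, the second, the third and the fifth comparison and 2 for the interaction. Fitting only the groups compared gave 161, 73 and 320 in the first, the third and the fourth. The Wilcoxon test gave 0 in all 5, with 1826, 2270, 1293, 1657 and 2308 genes at an unadjusted p under 0.05. Its smallest adjusted p lay between 0.0623 and 0.148. With so few libraries per group, its p cannot be small enough to pass adjustment unless many genes reach the smallest value. The 0 calls therefore do not argue against the other counts. Quantile normalization raised the share of higher genes in the LY+FGF4 comparisons from 20.4, 28.5 and 23.1% to 40.3, 39.9 and 41.3%. The estimated read number as a covariate gave 6, 109 and 281 in the first 3 and 223 for LY+FGF4 against DMSO. Genes of mean TPM of at least 30 gave 256 for LY+FGF4 against FGF4 and 3 for the interaction. Without the 6 libraries under 9000 genes the counts were 130, 464, 169, 601 and 28 in the first, the second, the third, the fifth and the sixth comparison.

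The interaction called 1 list with a pseudocount of 0.1, 2 with library weights, 1 without the shallowest library of each FGF4-treated group and 5 without the 6 libraries. LY+FGF4 against FGF4 called 2 lists with the filter at TPM of 5 and 2 with mean TPM of at least 30, and LY+FGF4 against LY called 11 with the Y-linked genes.

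Among scores, primitive endoderm passed for LY+FGF4 against FGF4 with a pseudocount of 0.1 (-1.65) and the block (-1.07). FGF/ERK targets lost their call for LY+FGF4 against DMSO with a pseudocount of 0.1 (0.38), scaling to SD 1 (0.33) and no filter (0.51). They passed for FGF4 against DMSO with a pseudocount of 5 (0.33), the median (0.98), quantile normalization (0.56) and the block (0.52), and for LY+FGF4 against FGF4 with quantile normalization (0.48). Trophectoderm lost its call for FGF4 against DMSO with scaling to SD 1 (-0.67) and without the shallowest libraries (-0.95), and passed for LY against DMSO with the median (-1.04) and for LY+FGF4 against DMSO with the block (-0.98). FOXO targets passed for LY against DMSO with the median (0.59) and quantile normalization (0.31), and for FGF4 against DMSO with the latter (0.28). The lineage balance passed for LY against DMSO with no filter (0.57). Without the 6 libraries, the differences that follow no longer passed after adjustment. LY+FGF4 then held only replicates 6 and 7, so its exact tests have few assignments and can hardly pass. For LY+FGF4 these losses do not show smaller effects. LY against DMSO kept all its libraries, and its result changed only through the adjustment over the other tests. Epiblast gave -1.83 for FGF4 against DMSO and -1.63 and -2.30 for LY+FGF4 against LY and DMSO. Primitive endoderm gave -1.13, 1.75 and 2.47 for LY and FGF4 against DMSO and LY+FGF4 against LY. Trophectoderm gave -0.86 for FGF4 against DMSO, FGF/ERK 0.98 and 0.61, and the balance -4.10 and -3.64 for LY+FGF4 against LY and DMSO. The r of FGF4 effects was 0.52 with a pseudocount of 5.

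Some directions reversed without the 6 libraries, where LY+FGF4 held only replicates 6 and 7. Tent5c was -0.15 for LY+FGF4 against FGF4 and Uvrag 0.22 for LY+FGF4 against LY. The p53 list had a mean of -0.31 for LY+FGF4 against FGF4, and the G2/M list -0.53, -0.47 and -0.28 for LY+FGF4 against FGF4, LY and DMSO. For the interaction the G2/M mean was -0.73, against -0.08 in the main fit, so it kept its sign.

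Leaving out each library in turn gave 16 to 49, 114 to 432, 283 to 581, 523 to 865, 671 to 1284 and 2 to 11 genes. Without DMSO replicate 3 they were 20, 177 and 760 (the first, the second and the fifth) and 3 for the interaction, without DMSO replicate 6, 27, 144 and 671, without replicate 7, 114 and 726 (the second and the fifth), without replicate 8, 29, 756 and 3 (the first, the fifth and the sixth), and without replicate 9, 16 in the first. LY replicate 4 or 8 and LY+FGF4 replicate 3 took the interaction to 2 and 11, and FGF4 replicate 7 took LY+FGF4 against FGF4 to 283. LY+FGF4 against FGF4 called 2 to 5 lists and the interaction 0 to 3. Scores ranged from -0.85 to -0.57 for epiblast in LY against DMSO, and from -1.30 to -0.93 for primitive endoderm in LY+FGF4 against FGF4. Trophectoderm ranged from -0.57 to -0.30, -1.24 to -0.93, -0.97 to -0.37 and -1.40 to -0.80 in the first, the second, the fourth and the fifth comparison. FGF/ERK ranged from 0.48 to 0.68 for LY+FGF4 against DMSO. The trophectoderm call for FGF4 against DMSO was lost in 9 of 13 of these runs, and the FGF/ERK call for LY+FGF4 against DMSO in 10 of 11.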

Other observations

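A small set of genes moved the same way with LY whether or not FGF4 was present. The 6 that rose in both backgrounds were Ftl1 (log2 fold change 1.28 without FGF4 and 1.01 with it), Fth1 (1.18 and 1.17), Arl6ip1 (1.37 and 1.14), Rogdi (1.05 and 1.07), Mlf2 (0.71 and 0.75) and Cd9 (0.66 and 0.47). Ftl1 and Fth1 encode the ferritin chains, and Cd9 a tetraspanin of the cell surface. Of the 15 that fell in both, 6 belong to the ATF4 and amino acid list, Nupr1, Chac1, Trib3, Mthfd2, Psat1 and Slc3a2, and Fdps to the sterol list. The others were Tars, a threonyl-tRNA synthetase gene (-1.16 and -1.05), Slc25a5, a mitochondrial ADP/ATP carrier gene (-1.09 and -0.91), Hax1 (-1.24 and -1.62), Anp32b (-0.70 and -0.72), Akr1b8 (-2.14 and -1.83), Aldh1b1, Eml1 and Slc5a11. Cd9, Slc3a2, Tars, Slc25a5, Hax1, Anp32b, Akr1b8 and Eml1 fall outside the rule for named genes and were named after their values were seen.

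12 of the 26 lists were called in none of the 6 comparisons, although FOXO targets, glycolysis, oxidative phosphorylation and WNT targets passed in some of them under other settings. FOXO targets, which PI3K signalling is known to restrain, had a smallest adjusted p of 0.0919, and their score differed by 0.14 between LY and DMSO (exact permutation test, adjusted p = 0.267) and by -0.27 between LY+FGF4 and FGF4 (exact permutation test, adjusted p = 0.195). The smallest adjusted p of a list was 0.0585 for glycolysis, 0.0684 for oxidative phosphorylation, 0.0784 for WNT targets, 0.245 for components of the PI3K pathway and for the unfolded protein response, 0.283 for immediate early and heat shock genes, and 0.303 for apoptosis regulators. It was 0.377 for components of the FGF pathway, 0.446 for core naive pluripotency, 0.488 for formative pluripotency and 0.727 for BMP/TGF-beta targets. Klf17, the 1 tested member of the cleavage-stage list, rose in LY+FGF4 against FGF4 (2.52, limma adjusted p = 0.0466), a call that was lost in 12 of 14 runs that left out 1 library. In called lists the median, the mean and the test had the same sign. In some others they did not, as for glycolysis in LY+FGF4 against FGF4, with a median of -0.19 and a test toward higher values.

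The lists overlap in part. Of their members, 10 of 32 primitive endoderm genes, 8 of 24 basement membrane genes, 5 of 20 epiblast genes, 4 of 32 ATF4 genes and 2 of 26 trophectoderm genes are in another list, so their tests are not independent. ICMs after immunosurgery hold no outer layer where the lysis was complete, and the trophectoderm list was still measured in every group, with scores of 4.77 ± 0.46 in DMSO, 4.34 ± 0.23 with LY, 3.72 ± 0.65 with FGF4 and 3.66 ± 1.00 with both. The ICM itself also expresses members of that list.

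In each pairwise comparison the real split was the 1 of 100 that gave as many genes past the threshold. The other splits mixed libraries of the 2 groups, which also evens out their spread. They therefore argue against a chance split of alike libraries, but not against false calls from the unequal spread of the groups. The real counts and the highest of the other splits were 45 and 3 for LY against DMSO, 294 and 76 for FGF4 against DMSO, 427 and 128 for LY+FGF4 against FGF4, 758 and 151 for LY+FGF4 against LY, and 1143 and 588 for LY+FGF4 against DMSO. For the number of lists called, FGF4 against DMSO narrowly passed the bound set beforehand. There 4 of 100 splits, the real one among them, called as many as 8, and the highest other split called 8. Since other splits reached the real number, and 6 such numbers were tested, chance is not excluded. The bound was not passed for LY against DMSO (6 lists, 17 of 100 splits, highest other 10), LY+FGF4 against FGF4 (4 lists, 25 of 100, highest 9), LY+FGF4 against LY (7 lists, 15 of 100, highest 12) and LY+FGF4 against DMSO (7 lists, 18 of 100, highest 10). The interaction called 0 lists, which all 100 splits reached, and the highest other split called 9.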
